A study of Caenorhabditis elegans with 2 samples.

How the data were processed

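Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole Caenorhabditis elegans hermaphrodites at the first larval stage (L1), collected 6 h after synchronization. Per the labels, the animals carried an integrated transgene that expresses the T-box transcription factor TBX-2 with a C-terminal GFP-FLAG tag, and the precipitation used an antibody against GFP. Both samples belong to 1 group and are biological replicates 1 and 2 in the labels, so no comparison between conditions was possible. Replicates were compared with each other mainly at the peaks of a list made from both of them, so the comparison is not independent of that list.

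The deposited files are peak lists. For each replicate, and for both replicates pooled, the authors deposited a list of 30000 regions that contains peaks and background. These lists served as input to an irreproducible discovery rate (IDR) step, which assesses how alike regions rank in replicates. A further list, thresholded by IDR, was made from the same data. It held the strongest regions of the pooled list, so a single peak in it need not rank alike in the replicates. Each list exists on 2 assemblies, ce10 and ce11, per the notes deposited with the samples, and those notes derive the lists from the replicate alignments and a control alignment. The aligner, the peak caller, the IDR threshold and the strain of the control were not given in the sources used here. The peak signal in the deposited lists is the strength of a region as the authors' caller gave it, on a scale that is not stated, and it was used only to rank and describe peaks. The significance field in the deposited lists is a −log10 q-value. It takes 1 value, 4.01, for all peaks of the ce11 IDR list, so it could not rank them. The p-value field was empty and no IDR value was listed. No read counts were used, so the depth of each sample is unknown, and the intervals given for shares of peaks cover the counting of peaks only. Signal tracks and control reads were not analysed here.

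Each region was represented by its summit. Coordinates are on ce11, counted from 1, and gene models are those of Ensembl release 115 for WBcel235, whose chromosome names and lengths fit the ce11 lists. The 6 nuclear chromosomes (100.3 Mb) carry 19973 protein-coding genes with 29314 transcript starts. A promoter was defined as 1000 bp upstream to 200 bp downstream of a protein-coding transcript start, and a summit lying in the promoters of 2 genes was assigned to both. Regions of different lists were matched by the nearest summit within 100 bp, which need not be the strongest region nearby. Recovery by a replicate was measured among as many of its strongest regions as there are IDR peaks. Shares of summits in promoters or within 200 bp of non-coding RNA genes were compared with 1000 random placements on the same chromosomes by a two-sided permutation test, whose smallest possible p is 0.002. The share of peaks on a chromosome was compared with its share of protein-coding genes by an exact two-sided binomial test. Sequence motifs were searched on both strands within 50 bp of the summit and compared with a window of the same width centred 300 bp to one side of the same peak, by exact two-sided McNemar tests with Benjamini-Hochberg adjustment over 14 motifs. Words of 6 bases were tested in the same way. The share in 20 sets of summit windows shuffled with their dinucleotide counts kept was computed as a control for base composition. For each of 33 gene lists, the number of genes with a promoter peak was compared with all protein-coding genes by two-sided Fisher exact tests with Benjamini-Hochberg adjustment at a threshold of 0.05. Of the names in the lists, 4 (ceh-26, abu-3, elt-5 and daf-21) were not found in the annotation. Intervals are 95% exact Clopper-Pearson intervals for shares and conditional exact intervals for odds ratios.

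Tests, gene lists, motifs and the alternatives were chosen before the data were examined, except where stated. The genes and peaks named in the text are the 15 IDR peaks with the highest mean rank percentile in the 2 replicate lists, tbx-2 and unc-119, every member of a list of candidate TBX-2 targets, up to 4 members with the strongest promoter peak in each gene list past the threshold, and the 6 IDR peaks whose rank percentile differed most between replicates. These 6 were taken from the IDR peaks matched in both replicate lists. Others are named where a small group is given in full, or after their values were seen, as stated there. Alternatives included each replicate's own list alone, the 2192 strongest IDR peaks, narrower and wider promoters (500 bp upstream to 100 bp downstream, and 2000 bp upstream to 200 bp downstream), other overlap rules, other motif windows and backgrounds, assignment to the nearest transcript start within 2000 bp, and 10000 random gene lists matched on the length of the upstream intergenic region in 10 classes. The tests were first run on simulated data. With 4384 random summits, the promoter share was 0.98 times the random expectation, and no 6-base word was called among 2080. Of 10 simulated gene lists with raised binding all 10 were called, and of 20 without it 0 were. The simulated lists were larger than the pharyngeal and candidate lists, and their binding was raised more strongly. These calls therefore do not show the power of the test for such small lists. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.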

Results

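TBX-2 is a T-box transcription factor with a known role in the development of pharyngeal muscle. Its binding was mapped by anti-GFP ChIP-seq in whole L1 larvae that express a tagged copy, with 2 biological replicates and no second condition. The values below describe where the tagged protein was recovered, which genes lie there and how far the replicates matched. The lists hold no read counts, so the depth behind each peak is unknown.

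The ce11 IDR list held 4384 peaks on 6 chromosomes, with a median width of 400 bp and a median signal of 145. The strongest peak of the list, and of each replicate, lay 284 bp upstream of a transcript start of rpl-3, which encodes a protein of the large ribosomal subunit (chromosome III, 3867325 to 3867770, promoter, signal 1894). Its signal was 679 in replicate 1 and 1215 in replicate 2. Among the 15 peaks with the highest mean rank in both replicates, others lay in promoters of ribosomal protein genes as well, at rpl-35 (signal 1477), at rpl-20, whose promoter overlaps that of Y17G9B.5 (1461), and at rpl-15 (1360). The remainder included tasp-1, a threonine aspartase gene (1684), egg-5 (1550), cdc-48.1, which encodes an AAA ATPase (1506), tag-340 (1414), ZK1248.17 (1416), puf-9, a Pumilio family gene (1281), and the promoter shared by C47E8.4 and the chaperone gene hsp-90 (1226). The egg-5 and ZK1248.17 summits also lay within 200 bp of an annotated snRNA gene. For ZK1248.17 the summit lay 719 bp downstream of its nearest start, so its promoter class came from another transcript start. Introns held 3 of the 15, in Y111B2A.12 (1451), in pqn-41 (1315) and in sax-2, the neighbour of tbx-2 (1399). The peak nearest to cmd-1, the calmodulin gene, was intergenic, 4762 bp upstream of its start (1402).

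The replicates recovered largely overlapping sets of sites. Among its 4384 strongest regions, replicate 1 held 87.3% of the IDR peaks (3828, 95% interval 86.3 to 88.3) and replicate 2 held 91.8% (4023, interval 90.9 to 92.6). Both together held 80.2% (interval 79.0 to 81.4), where random placement gave 0.657%. Because the IDR list was made from these replicates, the shares are not independent evidence for the peaks. Across the 4260 IDR peaks matched in both whole lists, log2 signal correlated with Spearman's rho 0.844 and Pearson's r 0.880, where peaks are not independent replicates. The median over peaks of the ratio of replicate 2 to replicate 1 signal was 1.61, and 1 region had identical borders in both lists, with no summit of equal signal. No match was found in the list of replicate 1 for 91 IDR peaks. For 37 none was found in that of replicate 2, and 4 were matched in neither. The nearest summit within 100 bp was taken, so a stronger region farther off was passed over. For example, the IDR summit at 5127186 on chromosome III met a replicate 1 summit at 5127267 (signal 12.7). A stronger one at 5127061 (46.8) was out of reach. Missing matches and rank gaps can therefore reflect displaced summits as well as weaker signal. Among matched peaks, ranks differed most for an intronic one in unc-1, at 29696 in replicate 1 and 3622 in replicate 2. It was followed by an intronic one in scd-1, at rank 4102 and rank 29097. The next 4 ranked higher in replicate 2, in the promoters of zak-1 (rank 24163 against 2413) and gldi-2 (23568 against 2624), in a coding exon of lelo-2 (22339 against 2988) and upstream of somi-1 (20299 against 3281).

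**Figure D1:**
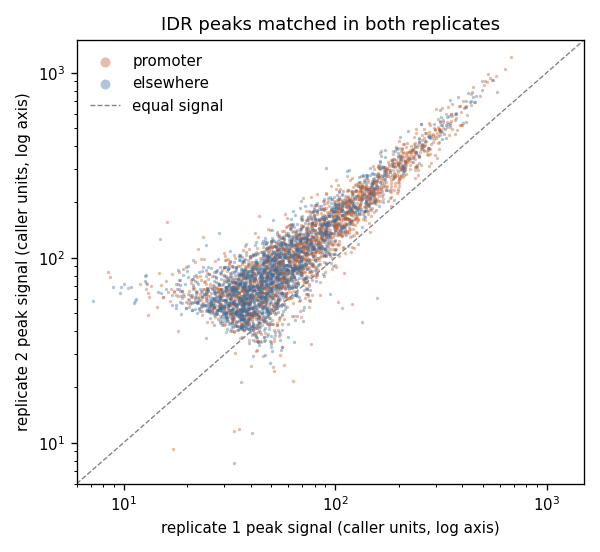
Peak signal of the 4260 IDR peaks matched in both replicates, replicate 1 on the x axis and replicate 2 on the y axis, both in the caller's units on log axes, with promoter peaks and peaks elsewhere in different colours and a dashed line at equal signal. Most points lie above the line, with a median ratio of 1.61, and Spearman's rho is 0.844.

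Most peaks lay at promoters of protein-coding genes. Of the 4384 summits, 56.7% fell in a promoter window (2487, interval 55.2 to 58.2), against the 25.7% given by random placement (permutation p = 0.002, the smallest possible). Coding exons outside promoters held 0.570% of summits against 18.8% at random, and 3′ UTRs held 0.525% against 2.39%, both at the same p. These classes exclude each other, so a higher promoter share lowers the rest. Among the 1897 summits outside promoters, introns held 37.3%, as at random, and intergenic sequence 59.4% against 33.5%. The median distance to the nearest protein-coding transcript start was 546 bp. The promoter share was 64.4% among the 2192 strongest peaks and 49.1% among the others. The 2487 promoter peaks lay at 3114 genes, 15.6% of the 19973 annotated protein-coding genes, and 773 summits lay in the promoters of more than 1 gene. With the 2192 strongest peaks alone, 1896 genes had a promoter peak.

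The X chromosome carried 867 peaks, 19.8% of the list, against 13.7% of protein-coding genes (exact binomial p = 7.44e-29). Chromosomes III (16.9% of peaks, 13.2% of genes, exact p = 6.08e-12) and I (17.2%, 14.4%, p = 4.26e-07) also held more peaks than their share of genes. V (15.5% of peaks, exact p = 1.52e-52) and II (14.5%, 17.3% of genes, p = 7.11e-07) held fewer, and IV held 16.2% with 16.4% of genes (p = 0.729). Per Mb of sequence, III had the most peaks (53.6), then I (49.9) and X (48.9), and all 3 exceeded their share of assembly length (exact p = 5.96e-09, 0.000110 and 0.000313). Promoters held 44.1% of the peaks on X, and between 56.8% on IV and 62.4% on I for the autosomes.

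Genes of basic cell functions were bound far more often than other genes. Of 76 ribosomal protein genes, 66 had a promoter peak (86.8%, interval 77.1 to 93.5), 5.57 times the share among all genes (adjusted exact p = 9.17e-42). With the nearest start the fold was 3.42, and among the 2192 strongest peaks 7.90. The proteasome list followed with 21 of 33 (4.08-fold, adjusted exact p = 2.61e-09), translation factors and tRNA ligases with 41 of 71 (3.70-fold, adjusted p = 5.14e-15), and oxidative phosphorylation with 30 of 53 (3.63-fold, adjusted p = 4.50e-11). Cell cycle genes had 21 of 43 (3.13-fold, adjusted exact p = 1.38e-06). Beside the ribosomal protein genes already named, the strongest members were the proteasome genes rpn-3 (signal 644), rpn-11 (418), rpt-2 (382) and pas-4 (299). In the respiratory chain they were cox-5A (1202), atp-1 (667), cox-6B (475) and cox-5B (467), and among translation genes iff-2 (1036), eif-3.C (849), eif-3.B (845) and eef-2 (738). The cell cycle list was led by lin-54 (1042) and pcn-1, which encodes the sliding clamp of DNA replication (935), followed by lin-53 (675) and cdk-5 (670). The lin-54 summit was also the one assigned to rpl-12. For 43 of the 66 bound ribosomal protein genes, the strongest summit also lay in the promoter of a gene outside the list. So it did for 14 of 21 bound proteasome, 18 of 30 oxidative phosphorylation, 24 of 41 translation and 12 of 21 cell cycle genes.

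**Figure D2:**
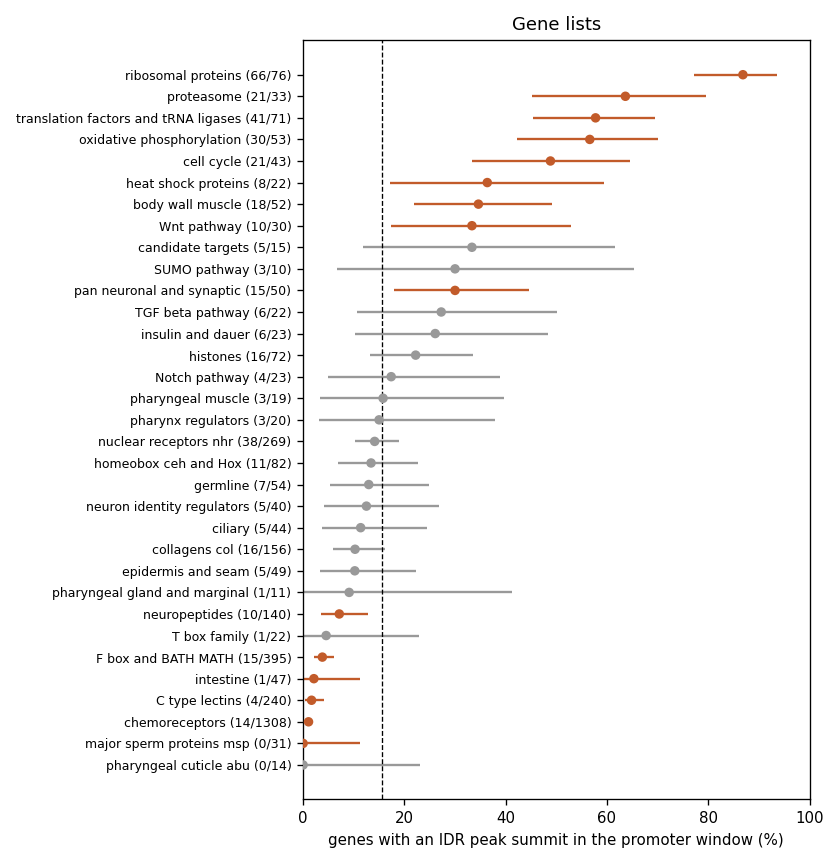
Share of genes in each of 33 lists with an IDR peak summit in the promoter window, in percent, with 95% exact intervals and the number bound over the list size, where lists past an adjusted p of 0.05 are coloured and the dashed line marks the 15.6% of all protein-coding genes. Ribosomal protein genes stand highest at 86.8% and chemoreceptor genes at 1.07%.

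Body wall muscle, synaptic and pan-neuronal, and Wnt pathway genes were bound about 2 times as often as other genes. Body wall muscle genes had 18 of 52 bound (2.22-fold, adjusted exact p = 0.00264), led by the calponin gene cpn-3 (signal 477), the cofilin gene unc-60 (199), the myosin light chain gene mlc-2 (149) and the troponin T gene mup-2 (141). The median signal at bound body wall muscle genes was 94.7, against 176 over all bound genes, and among the 2192 strongest peaks the list was at 0.608-fold (adjusted exact p = 0.587). Of 50 synaptic and pan-neuronal genes, 15 were bound (1.92-fold, adjusted exact p = 0.0265), led by the liprin gene syd-2 (320), ric-19 (255), maco-1 (245) and ric-3 (229). This list was at 1.29-fold with the narrower promoter (adjusted exact p = 0.554), 1.90-fold among the 2192 strongest peaks (0.128) and 3.56-fold with the nearest start (3.89e-09). In the Wnt pathway 10 of 30 were bound (2.14-fold, adjusted exact p = 0.0412), led by the Dishevelled gene mig-5 (859) and followed by the β-catenin genes wrm-1 (367) and sys-1 (192) and the kinase gene lit-1 (173). The Wnt list was at 1.71-fold without replicate 1 (adjusted exact p = 0.240), 1.405-fold among the 2192 strongest peaks (0.618) and 1.34-fold with the narrower promoter (0.554). Heat shock protein genes had 8 of 22 bound (2.33-fold, adjusted exact p = 0.0336), at strong peaks next to hsp-90 (1226), hsp-60 (1106), hsp-3 (871) and hsp-1 (822). Heat shock genes were at 2.05-fold against lists matched on upstream length (adjusted permutation p = 0.127). They were at 1.55-fold with the nearest start (adjusted exact p = 0.451), 2.05-fold with the wider promoter (0.0528) and 1.98-fold with the 5737 strongest pooled regions (0.0911).

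Chemoreceptor, F-box, C-type lectin, intestinal, sperm protein and neuropeptide genes were bound less often than other genes. Only 14 of 1308 chemoreceptor genes had a promoter peak (0.0687-fold, 0.0369-fold with the narrower promoter, adjusted exact p = 7.54e-76), as did 15 of 395 F-box and BATH or MATH domain genes (0.244-fold, adjusted p = 5.21e-13) and 4 of 240 C-type lectin genes (0.107-fold, 0.0671-fold with the narrower promoter, adjusted p = 3.65e-12). The strongest members were srh-2 (signal 638), sri-5 (524), srh-16 (513) and srh-89 (246) among chemoreceptors, and fbxb-85 (788), fbxa-90 (553), bath-42 (370) and bath-36 (305) in the F-box group. The fbxa-90 peak was also the one assigned to efl-1. The 4 lectin genes were clec-126 (185), clec-53 (184), clec-104 (141) and clec-87 (102). For 10 of the 14 chemoreceptor genes the strongest summit was not theirs alone. It also lay in the promoter of a gene outside the list or within 200 bp of a tRNA, snRNA or snoRNA gene. The same held for 10 of the 15 bound genes of the F-box group and for all 4 lectin genes. Intestinal genes had 1 of 47 bound, erm-1 (141), at 0.136-fold (adjusted exact p = 0.0219), and major sperm protein genes 0 of 31 (interval up to 11.2%, adjusted p = 0.0267). Neuropeptide genes had 10 of 140 bound (0.458-fold, adjusted exact p = 0.0153), led by ins-39 (690), nlp-4 (154), flp-23 (106) and nlp-31, whose peak ranked 3207. Neuropeptide genes were at 0.554-fold against lists matched on upstream length (adjusted permutation p = 0.102), 0.635-fold with the nearest start (adjusted exact p = 0.149) and 0.150-fold among the 2192 strongest peaks (0.000791). The intestinal list was not past the threshold among the 2192 strongest peaks (0-fold, adjusted exact p = 0.0567) or with the narrower promoter (0.171-fold, 0.0690). The sperm protein list was not past it in these settings (0-fold in both, adjusted exact p = 0.220 and 0.0690) or with the nearest start (0.441-fold, 0.403).

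The lists closest to the known role of TBX-2 in the pharynx did not differ detectably from other genes, apart from single alternatives. Pharyngeal muscle genes had 3 of 19 bound, namely the NK-2 homeobox gene ceh-22 (signal 139) and the myosin genes myo-2 (83.3) and myo-1 (82.0), at 1.01-fold with an odds ratio interval of 0.189 to 3.55 (adjusted exact p = 1). Of 20 pharynx regulators 3 were bound, tbx-2, peb-1 (151) and ceh-22 (adjusted exact p = 1), and of 10 SUMO pathway genes 3 were, namely smo-1, ubc-9 and uba-2 (1.92-fold, adjusted p = 0.293). Pharyngeal gland and marginal cell genes had 1 of 11 bound and the abu cuticle genes 0 of 14 (adjusted exact p = 1 and 0.243). Among 15 candidate targets fixed in advance, 5 had a promoter peak (2.14-fold, odds ratio interval 0.726 to 8.71, adjusted exact p = 0.146). Assignment to the nearest start took the candidate list past the threshold (2.74-fold, adjusted exact p = 0.0327). Against lists matched on upstream length it did not pass (2.53-fold, adjusted permutation p = 0.162). Use of the 5737 strongest pooled regions took pharyngeal muscle genes past the threshold (2.30-fold, adjusted exact p = 0.0307). The 5 candidates bound were tbx-2 itself (925), ubc-9, which encodes the SUMO-conjugating enzyme (263), smo-1, which encodes SUMO (222), ceh-22 and myo-2. Here and among pharynx regulators tbx-2 was counted as bound, although extra copies from the transgene stay open for its locus. In the promoters of pha-4 and gei-17 the strongest region of the pooled list ranked 7495 and 9261 of 30000, below the IDR threshold. Those of lag-1 (19972), tbx-38 (17219) and tnt-4 (16542) ranked lower still. No pooled region fell in the promoters of D2096.6, ceh-24, glp-1, hlh-6 or tbx-37. Outside the promoter windows, IDR peaks lay within 5 kb of gei-17 (3), pha-4, lag-1 and ceh-24 (2 each) and hlh-6 (1). Within that distance D2096.6, glp-1, tbx-37, tbx-38 and tnt-4 had 0.

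None of the other lists passed the threshold in the main comparison. The TGF-β pathway had 6 of 22 bound (adjusted exact p = 0.243), insulin and dauer genes 6 of 23 (0.246), Notch pathway genes 4 of 23 (0.880) and histone genes 16 of 72 (0.243). Neuron identity regulators had 5 of 40 (0.909), homeobox genes 11 of 82 (0.880), nuclear receptor genes 38 of 269 (0.703) and T-box genes 1 of 22, which was tbx-2 (0.340). Ciliary genes had 5 of 44 (0.703), epidermal and seam genes 5 of 49 (0.589), germline genes 7 of 54 (0.867) and collagen genes 16 of 156 (0.146). Assignment to the nearest start took the TGF-β list (2.49-fold, adjusted exact p = 0.0268) and the insulin and dauer list (2.38-fold, 0.0308) past it. Against lists matched on upstream length neither passed (2.24-fold and 1.91-fold, adjusted permutation p = 0.162 and 0.283). Epidermal and seam genes passed among the 2192 strongest peaks (0-fold, adjusted exact p = 0.0425) and collagens with the wider promoter (0.579-fold, 0.0153). In total 15 of 33 lists passed, 9 with more and 6 with fewer bound genes than expected.

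The tbx-2 gene (WBGene00006543, chromosome III, 5130923 to 5136296, minus strand) lay in the densest cluster of peaks. Within 20 kb of its start were 18 IDR peaks, against a median of 3 and a maximum of 13 around 3105 other genes with a promoter peak. Left out of these were 8 neighbours whose windows overlap that of tbx-2 and share its peaks, with up to 14. Of the 18 peaks, 14 lay in introns, 4 in promoters and 0 in coding exons, counting all genes in the window. Inside tbx-2 itself lay only the summits at 5133424 and 5134682. Most of the 18 lay within the spans of the neighbours sax-2 (5109701 to 5130676) and Y54H5A.2 (5137358 to 5149578). The strongest (signal 1399, summit at 5129355) lay in an intron of sax-2, downstream of tbx-2. The strongest in the tbx-2 promoter (925, summit at 5136398) ranked 39 in replicate 1 and 76 in replicate 2. In the replicates' lists of 30000, a mean of 42 regions lay within 20 kb of the start, against a median of 15 and a maximum of 44.5 around the other genes. At unc-119, whose mutant allele is in the strain's genotype, no IDR peak fell in the promoter, where the strongest pooled region ranked 7305. The nearest IDR summit ranked 4023 and lay 739 bp from an unc-119 transcript start. A mean of 21 replicate-list regions lay within 20 kb.

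**Figure D3:**
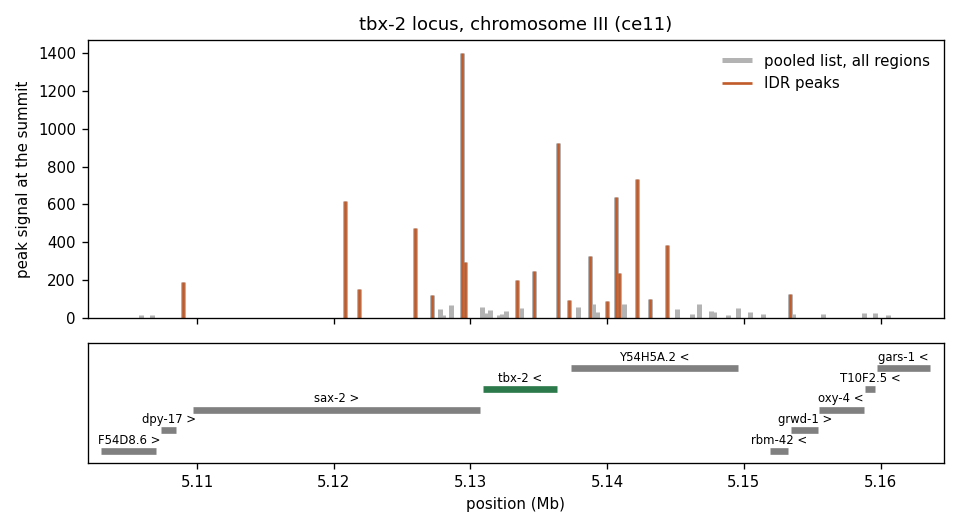
Map of the tbx-2 locus on chromosome III in ce11, position in Mb on the x axis, with a vertical line at each summit whose height is its signal in the caller's units (orange, IDR peaks; grey, other regions of the pooled list), above the protein-coding genes with their strand as an arrowhead. The 2 highest lines stand at 5129355 (1399) and 5136398 (925).

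No enrichment of the T-box site GGTGTGA was detected at the summits. It lay within 50 bp of 42 of 4384 summits (0.958%, interval 0.691 to 1.29) and in 0.753% of the flanking windows, a ratio of 1.27 (exact McNemar p = 0.349, adjusted p = 0.543). The interval of the ratio of peaks with the site at one window only, 0.787 to 2.102, leaves room for a doubling. The shorter core GGTGTG was at 228 summits and 108 flanks, 2.11-fold (exact p = 2.27e-11). Base composition differed as well, with 46.1% G and C at summits and 35.3% in the flanks, and the core was 1.18 times as frequent at summits as in 1 set of windows shuffled with their dinucleotides kept (exact p = 0.0766), and GGTGTGA had a mean share of 1.27% over 20 such sets.

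Other sequences marked the summits. The repeat GAGAGA lay within 50 bp of 28.2% of summits and in 6.30% of flanks (4.49-fold, adjusted exact p = 9.22e-166), and in 13.0% of shuffled windows. The E-box CACGTG was at 6.52% against 2.08% (3.14-fold, adjusted exact p = 1.42e-24), the E-box CAGCTG at 147 summits against 86 flanks (1.71-fold, adjusted p = 0.000137) and the E2F site TTCCCGC at 2.30% against 1.23% (1.87-fold, adjusted p = 0.000263). Lower shares than in the flanks were found for the homeodomain site TAATTA (0.412-fold, adjusted exact p = 2.07e-14), the MEF2 site (0.233-fold, adjusted p = 1.33e-07) and the CSL site TGGGAA (0.696-fold, adjusted p = 0.000191). The NK-2, GATA, forkhead, AP-1, X-box and Hox-Pbx sites did not differ detectably from the flanks. A single set of shuffled windows, which keep the composition of the summits, gave other ratios for several of these sites. Against it TAATTA was at 1.33-fold (adjusted exact p = 0.0919) and CSL at 0.980-fold (0.875). MEF2 was at 3.50-fold (adjusted exact p = 0.0540), and at 2.04-fold against the mean of 20 sets. The forkhead site was at 1.90-fold (adjusted exact p = 7.81e-38) and GATA at 1.95-fold (0.000723), while AP-1 was at 0.514-fold (0.00154). Of 2080 words of 6 bases, 810 were more and 610 less frequent at summits than in flanks. Against 1 set of shuffled windows, a control added after the data were seen, 376 were more and 707 less frequent, and 259 were more frequent in both comparisons. Among the more frequent words, the lowest p values after GAGAGA and its shifted form belonged to ACGCAG (15.9% against 1.89%) and CGTCTC (18.2% against 3.13%).

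**Figure D4:**
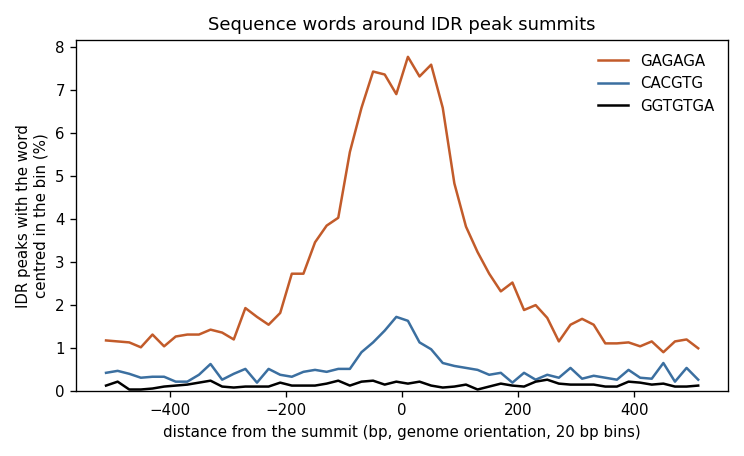
Share of the 4384 IDR peaks, in percent, with each word centred in a 20 bp bin at the given distance from the summit in bp. GAGAGA and CACGTG rise towards the summit, and GGTGTGA stays below 1% throughout.

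Summits were also concentrated at genes of short non-coding RNAs. Within 200 bp of a tRNA gene lay 168 summits (3.83%), 13.6 times the random share of 0.282% (permutation p = 0.002). Of 612 tRNA genes, 179 had a summit within 200 bp. With a distance of 500 bp in place of 200 bp, the ratio of summits to random positions was 6.84. The corresponding figures were 1.98% for snoRNA genes (10.9-fold) and 0.547% for snRNA genes against a random share of 0.0608%, at the same p. No summit lay within 200 bp of the 20 rRNA genes, where 0.0156% was expected at random (permutation p = 1).

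On ce10 the IDR list held 5737 peaks, 1.31 times the number on ce11. On both assemblies the IDR peaks were exactly the strongest regions of the pooled list. The weakest IDR peak had a signal of 58.3 on ce10 and 76.8 on ce11. At or above the weakest ce11 signal the ce10 pooled list held 4382 regions, against 4384 on ce11, so that the lists differed in the signal at which they end.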

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

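The tests of coding exons, of other transcription factor genes and of unc-119, and the description of regions just below the IDR threshold, were chosen only after results for the tbx-2 locus or the pooled list had been seen.

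Signal lay in regions outside the IDR list of 4384 peaks. The 1353 regions of the ce11 pooled list ranked from 4385 to 5737, just below the IDR threshold, had their summits in promoters in 41.5% of cases, against 25.7% at random. GAGAGA lay within 50 bp of 22.5% of their summits, against 6.21% of flanks, and 90.5% were matched in both replicate lists. Among the last 10000 regions of the pooled list, 3.77% were matched in both.

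The cluster of 18 peaks at tbx-2 was weighed first. The 372 other homeobox, T-box and nuclear receptor genes, bound or not, had a median of 1 and at most 7 IDR peaks within 20 kb. So high a density was therefore not shared by these families as a whole. Only 23 of 3105 other bound genes had 9 or more, so the comparison cannot tell bound transcription factor genes from other bound genes. A second test, chosen after that one, asked whether the regions avoid coding exons. It did not decide, because the summit lay in a coding exon for 13.95% of the 43 pooled regions, with an interval of 5.30 to 27.9 that holds both the 14.3% of the rest of the list and the 24.4% of the sequence that is coding. Extra copies from the transgene stay open, with the count of replicate-list regions at the 99.97th percentile of other bound genes. For unc-119 the counts decide nothing, with a percentile of 49.2 within 3 kb and a count within 20 kb of 21, above the median of 15. The span of the transgene and the origin of its marker were not given in the sources used here, and no biological explanation beyond these counts of sites was tested.

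The T-box motif was weighed against base composition. GGTGTGA at summits was 0.757 times its mean share in shuffled windows, so that base composition alone could account for its small excess over flanks. Binding through other proteins and binding at sites that this consensus misses were not tested, nor was any other biological explanation.

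Peaks at promoters of housekeeping genes were weighed last. Enrichment of very active loci whatever protein is tagged stays open, in line with the 13.6-fold concentration at tRNA genes, which are transcribed by another polymerase. Binding at accessible promoters that lack the T-box motif cannot be told apart from other binding, because 0 of 85 ribosomal protein and proteasome promoter peaks and 27 of 2402 other promoter peaks had GGTGTGA (odds ratio 0, interval up to 4.18, exact Fisher p = 1). The core GGTGTG was at 8.24% of the former and 5.70% of the latter (exact p = 0.338). Beyond these, no biological explanation was tested, and a precipitation with another tagged protein was not analysed here.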

How the results depend on the processing

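Alternatives that used the depth of the ce10 list on ce11, and the shuffled control for 6-base words, were added after seeing the data. The promoter, X chromosome and tRNA results kept their direction and side of the threshold under every alternative run, as did 5 gene lists with more bound genes (ribosomal proteins, proteasome, translation, oxidative phosphorylation and cell cycle) and 3 with fewer (chemoreceptors, F-box genes and C-type lectins). The IDR list falls to 2192 peaks, and genes with a promoter peak to 1896, when the weaker peaks are removed by construction. Recovery in both replicates was 83.3% with any overlap of 1 bp, 63.7% with a reciprocal overlap of 50% and 97.2% with whole lists, and with 1 replicate left out it ranged from 87.3% to 91.8%. Spearman's rho was 0.870 for the 2192 strongest peaks and 0.833 on ce10. The T-box ratio was 2.11 with GGTGTG, past the threshold. It fell below 1 with AGGTGTGA (0.857), among the 2192 strongest peaks (0.933) and against 1 shuffled set (0.667, exact McNemar p = 0.0460, adjusted p = 0.0716), and ranged from 0.696 to 1.18 with 1 replicate left out. Shuffled windows gave 376 enriched 6-base words in place of 810. For body wall muscle, the fold was 0.608 among the 2192 strongest peaks, below 1. Apart from the removal of weaker peaks, the cause was not tested. Among lists not past the threshold, the fold crossed 1 for pharyngeal muscle without replicate 1 (0.677, against 1.36 without replicate 2), among the 2192 strongest peaks (0) and with the narrower promoter (0.848). It did so for pharynx regulators among the 2192 strongest peaks (1.05), with the wider promoter (1.00), with the nearest start (1.37) and against matched lists (1.26). With the nearest start and with matched lists it also crossed for neuron identity regulators (1.54 and 1.09) and histones (0.9497 and 0.930), and with the nearest start for nuclear receptors (1.19). Over the single gene lists, 229 of the alternative values kept direction and side of the threshold, 16 fell short of it, 6 newly passed it and 13 changed direction. No paired analysis was possible because there was 1 group. Unknown read depth limits what can be said of weak peaks, since the caller's signal cannot be turned into counts.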

Other observations

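All tests in this part were chosen after the data were seen. Genes were grouped by name prefix alone, which gave 170 groups of at least 10 members. Such groups, among them lin, unc and tag, need not be families of related genes. Of the 170, 20 had more and 25 fewer bound genes than all protein-coding genes at an adjusted exact p under 0.05. Outside the lists of the report, nucleoporin genes (npp) had 17 of 26 bound (4.19-fold, adjusted exact p = 3.43e-07), DnaJ chaperone genes (dnj) 15 of 29 (3.32-fold, adjusted p = 0.000102) and vacuolar protein sorting genes (vps) 15 of 31 (3.10-fold, adjusted p = 0.000244). RNA-binding motif genes (rbm) had 9 of 13, vacuolar ATPase genes (vha) 10 of 20, RNA polymerase II subunit genes (rpb) 7 of 11 and Integrator genes (ints) 7 of 11. Mitochondrial ribosomal protein genes had 16 of 41 (mrpl) and 9 of 25 (mrps) bound, and cytoplasmic ones 37 of 45 (rpl) and 29 of 31 (rps), a difference that was not tested. Ligand-gated channel genes (lgc) had 0 of 56 bound and transthyretin-related genes (ttr) 1 of 58.

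Promoters of microRNA genes, taken with the same window, held 37 summits, 3.02 times the random share (permutation p = 0.002, the smallest possible), and 44 of 261 microRNA genes (16.9%) had one, against 15.6% of protein-coding genes. The summits at mir-354 (791) and mir-5549 (656) were also those assigned to rps-20 and eef-1A.1. Others lay at mir-52 (signal 337), mir-90 (323), mir-80 (200), mir-71 (161) and the muscle microRNA gene mir-1 (137). A single summit at signal 684 served mir-54, mir-55 and mir-56.

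The word of 8 bases with the lowest p value, AGACGCAG, lay within 50 bp of 458 summits (10.4%) and in 23 flanking windows (0.525%, 19.9-fold). It was at 10.9% of promoter summits and 9.80% of the others, but at 2 of the 168 summits next to tRNA genes. GAGAGA, in contrast, was at 29.2% of tRNA summits and 28.2% of all summits, and at 12.9% of the ribosomal protein and proteasome promoter peaks against 608 of 2402 other promoter peaks (odds ratio 0.439, exact Fisher p = 0.0101). Summits next to tRNA genes lay in the window of a protein-coding promoter in 24.4% of cases, and their median signal was 133 against 145 for all IDR peaks.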
